A study of Mus musculus with 27 samples.

How the data were processed

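Poly-A RNA was sequenced from 27 libraries of mouse CD8+ T cells in 9 groups of 3 libraries. The submitters' 2 gene count tables, each with 56860 features, were the starting point: 1 holds the unstimulated and day 2 libraries and the other the day 1 libraries. The library protocol in the labels selects poly-A RNA, primes with random hexamers and names no step that marks the strand; 150 bp paired reads were made on a NovaSeq instrument. Per the submitters' processing notes, the tools named are Trim Galore 0.6.5, STAR 2.7.6a and featureCounts 1.6.3, with genome build GRCm38. The values that the authors deposited are whole-number counts of reads per gene with no normalization, per the file headers, which are in the layout featureCounts writes. Whether counting used strand, and how reads with several alignments were treated, is not given in the sources used here. Totals per library ranged from 16421406 to 25378614 counts over all 27 libraries.

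The gene coordinates in the tables do not match the build named in the notes. Of 49100 symbols found on the same chromosome in the GENCODE M21 annotation of GRCm38, 1360 (2.77%) have the same start, so the positions printed here are those of the tables, with no build assigned. Of the features, 1606 carry no symbol. Of the 375 listed symbols, 2 were not found in the tables.

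Genes were kept with edgeR's filterByExpr, libraries were scaled by TMM, and differences were tested with edgeR 4.0.16's quasi-likelihood F test (glmQLFit with robust estimation, glmQLFTest) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested in the comparison. An adjusted p under 0.05 counted as past the threshold. Comparisons within 1 table used the groups of that table: 12 libraries and 15069 genes for the unstimulated and day 2 groups, and 15 libraries and 13786 genes for the day 1 groups. Comparisons across the tables, and the test of whether the V4 minus OVA difference changed between the days, used 1 fit over 27 libraries and 15630 genes. The tables go together with the days, so a preparation or sequencing batch cannot be told apart from time in these. Standard errors are for the log2 fold change, levels are CPM (edgeR cpm) after TMM scaling over all 27 libraries, and intervals are at 95%. No library is a near copy of another: the chi-square statistic per gene between replicates ranged from 3.18 to 34.2.

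Before the data were examined, 22 gene lists were fixed, covering glycosylation, T cell activation, metabolism, cell cycle and markers of other cell types. Each list with at least 5 tested genes was set against all other genes with camera in limma 3.58.1, with a preset correlation between genes of 0.01 and, as an alternative, with an estimated correlation. These camera p values were adjusted over the lists of a comparison. For each list the number of genes past the threshold is also given adjusted over the list alone.

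The rule for named genes was fixed in advance as well. St6gal1 is named in every comparison. In 8 main comparisons (OVA day 2 and OVA day 1 against naive, Q4 and V4 against OVA on each day, beads against OVA at day 1, anti-CD3 against beads) the 5 largest rises and 5 largest falls were taken. These had to be past the threshold, with a mean log2 CPM of at least 3 and no overlap between the 2 groups; predicted genes and receptor or immunoglobulin segments were left out. Up to 4 members of each list were named in order of p. Some results that this rule selects are not reported here. A gene named in another way is said to be chosen after its values were seen.

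Reads of near-identical genes may have been split or dropped by the counting, which makes the values of Slc28a2b, the granzyme, Ifit3 and Ifit3b, Klra and hemoglobin genes uncertain. Without strand, reads of overlapping genes on opposite strands cannot be told apart. Of 88 genes named, 24 share exon sequence in the tables with a gene on the opposite strand, among them St6gal1 (200 bp, with BC106179), Tg, Xcl1, Ccl3 and Cish, and Top2a shares 122 bp with a gene on the same strand.

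The procedure was tested on simulated counts with known changes. For V4 against OVA at day 2, with 14715 genes in the simulation, 39.4% of genes changed 1.5-fold, 71.2% of those changed 2-fold and 73.4% of those changed 4-fold were called, against 0.055% of unchanged genes. For V4 against OVA at day 1 (13481 genes) these were 56.9%, 74.6% and 90.8%, against 0.11%, for OVA day 1 against naive (15061 genes) 35.4%, 68.2% and 75.4%, against 0.027%, and for the change of the V4 minus OVA difference between the days (15048 genes) 30.2%, 54.1% and 71.2%, against 0.04%. The 1 changed list was called in each of the 4, and of the unchanged lists 1 of 20 was called in V4 against OVA on each day, 0 of 20 in OVA day 1 against naive and 0 of 21 in the last. The simulations changed few genes: for V4 against OVA at day 2, 14499 of 14715 were unchanged. In the real comparison 44.8% of genes passed, so the simulated shares need not hold there. Simulated genes were drawn independently, so the list check does not test the correlation between genes. Alternatives to each choice were DESeq2 1.42.0, RLE scaling, no filter on low counts, a fit with only the compared groups, a fit over all libraries, a replicate block, the estimated correlation, and leaving out each replicate in turn. The labels do not say whether replicates are separate animals or cultures, so p values measure only the spread between these samples, which may be technical. They also give no peptide doses.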

Results

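Gene expression was measured in naive splenic CD8+ T cells of OT-I mice, whose transgenic receptor recognises the ovalbumin peptide OVA, and in the same cells after stimulation in culture. The stated purpose was to follow St6gal1 during T cell receptor activation. Cells were left unstimulated (naive) or given OVA, or the altered peptides Q4 or V4, names in common use for OVA with glutamine or valine at the fourth residue, for 1 or 2 days. Further cells were stimulated for 1 day with beads carrying antibodies to CD3 and the costimulatory receptor CD28 (beads), or with immobilized antibody to CD3 alone (anti-CD3). Each of the 9 groups had 3 libraries, with 16421406 to 25378614 counts each. Naive replicate 1 had the fewest features detected, 14974, against 18497 to 21819 in the other libraries. Without it every comparison with naive gave more genes past the threshold, for example 11663 against 10865 for OVA at day 2. Adjusted p values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and those of gene lists are from camera.

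St6gal1, which encodes the enzyme that adds sialic acid in alpha-2,6 linkage to galactose on N-glycans, was highest in naive and bead-stimulated cells. In the count tables the gene lies on chromosome 16 from 23043490 to 23179100 on the + strand, with 4916 bp of exon. Naive libraries held 166 ± 10.4 CPM (SD, n = 3). OVA lowered it to 13.2 ± 3.73 CPM at day 1 and 15.2 ± 1.51 CPM at day 2, an 11.4-fold fall at day 2 (log2 fold change -3.51 ± 0.11 SE, adjusted p = 2.9e-14). Q4 gave 18.8 ± 3.02 CPM at day 1 and 15.7 ± 1.61 CPM at day 2, and V4 gave 53.6 ± 4.31 and 72.5 ± 9.32 CPM. Beads left 150 ± 24.2 CPM, a log2 difference from naive of -0.15 with an interval of -0.41 to 0.12 (adjusted p = 0.302), while anti-CD3 left 31.2 ± 2.28 CPM. Day 1 groups are set against naive across the 2 count tables, where batch cannot be told apart from time. CPM is a share of a library's reads, so changes per cell were not measured. The scaling takes most genes as unchanged, yet 72.1% of the genes tested passed in OVA day 2 against naive.

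**Figure D1:**
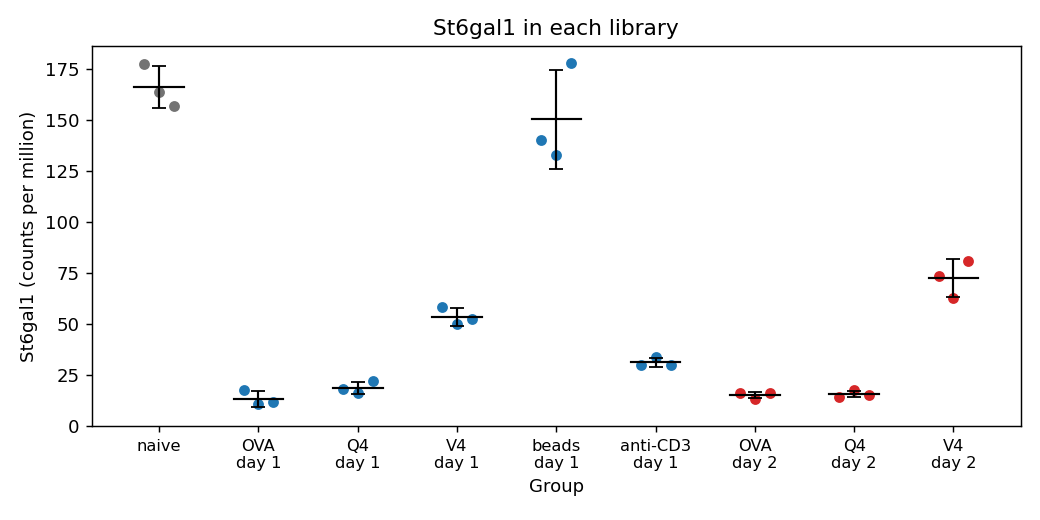
St6gal1 in CPM (vertical axis) in each of the 27 libraries, by group (horizontal axis); points are libraries (grey naive, blue day 1, red day 2), horizontal bars are group means and error bars are SD. Means run from 13.2 CPM in OVA day 1 to 166 CPM in naive cells, and beads (150 CPM) lie far above the other stimulated groups.

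Among the peptides, V4-stimulated cells held more St6gal1 than OVA-stimulated cells on both days, 4.07-fold at day 1 (adjusted p = 2.8e-09) and 4.91-fold at day 2 (adjusted p = 3.9e-11). They also held more than Q4-stimulated cells, 2.83-fold at day 1 and 4.67-fold at day 2. Q4 and OVA did not differ past the threshold: the log2 difference was 0.52 at day 1 (interval 0.18 to 0.86, adjusted p = 0.0611) and 0.07 at day 2 (interval -0.17 to 0.31, adjusted p = 0.915). The day 1 difference passed the threshold in DESeq2 (0.51), with no filter on low counts (0.52) and without OVA day 1 replicate 1 (0.77), and its adjusted p ranged from 0.000274 to 0.274 over the alternatives. Against OVA at day 1, St6gal1 was 11.5-fold higher with beads (adjusted p = 7.7e-13) and 2.42-fold higher with anti-CD3 (adjusted p = 5.2e-06). Anti-CD3 was 4.76-fold below beads (adjusted p = 3.2e-10). The peptide doses are not given, so these comparisons match the peptides by time only.

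Other genes of the sialic acid pathway moved in several directions after OVA. At day 2 against naive, 4 of 14 tested sialyltransferases rose and 7 fell (4 and 7 adjusted over the list alone). The list had a median of -0.261 and did not pass the list test (camera adjusted p = 0.199). St8sia1, a ganglioside sialyltransferase, fell by 2.45 ± 0.12 on the log2 scale, from 133 ± 21.1 to 25.4 ± 1.59 CPM. St6galnac4 rose by 1.83 ± 0.09 and St3gal4 by 1.42 ± 0.09. Cmah, which converts the sialic acid Neu5Ac to Neu5Gc, fell by 3.40 ± 0.07, from 813 ± 7.85 to 80.4 ± 2.05 CPM. Mgat5, which builds the branched N-glycans that galectins bind, fell by 2.09 ± 0.10, and Galnt3, which starts O-glycans, rose by 4.60 ± 0.17. The lists of sialic acid supply (3 rose and 3 fell of 8), N-glycan branching (7 and 7 of 17) and O-glycan synthesis (3 and 6 of 14) did not pass the list test (adjusted p = 0.153, 0.367 and 0.267), with 3 and 3, 7 and 7, and 3 and 6 adjusted over the list alone. For sialic acid supply the median was 0.125 while camera's direction was down.

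The first comparison asks what 2 days of OVA did to naive cells. Gzmb, the killing protease granzyme B, went from 4.44 ± 1.5 to 2930 ± 151 CPM (637-fold, adjusted p = 8.3e-17). Il2ra, the high-affinity interleukin-2 receptor chain, rose 139-fold, the cytokine gene Lif 1470-fold (976-fold without naive replicate 1) and Bcat1, an enzyme of branched amino acid breakdown, 140-fold. Tg, known as the thyroid hormone precursor thyroglobulin, rose 384-fold to 569 ± 48.9 CPM (648-fold without naive replicate 2). Klf2, the transcription factor that maintains quiescence and recirculation, fell 85.2-fold, the nucleoside transporter gene Slc28a2b 142-fold and the integrin gene Itgae 105-fold. Jchain and Lyz2, abundant in plasma cells and myeloid cells, fell 275-fold and 133-fold (57.0-fold for Lyz2 without naive replicate 3).

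Of 15069 genes, 10865 passed the threshold, 5563 higher and 5302 lower. All 20 G2/M genes rose (20 adjusted over the list alone, median log2 fold change 4.69), among them Top2a and Mki67, as did all 20 S phase genes, 20 of 20 ribosome biogenesis genes and 16 of 16 serine and one-carbon genes (20, 20 and 16 adjusted over the list alone), such as Psat1 (4.58 ± 0.08). In the T cell receptor activation list 16 of 20 rose and 2 fell (16 and 2 adjusted over the list alone), with Myc up by 3.54 ± 0.08, and in the naive list 16 of 20 fell and 3 rose (16 and 3 adjusted over the list alone), with S1pr1, the receptor for exit from lymphoid organs, down by 5.38 ± 0.12 and Tcf7 by 2.56 ± 0.07. These 6 lists held with an estimated correlation. Cholesterol synthesis genes (19 of 20 rose, 19 adjusted over the list alone) and effector genes (11 rose and 7 fell of 20, the same numbers adjusted over the list alone) passed the list test but not with an estimated correlation (adjusted p = 0.168 and 0.169 with an estimated correlation). Inhibitory receptors rose in 7 of 11 and fell in 3 (7 and 3 adjusted over the list alone), with Ctla4 up by 4.28 ± 0.08.

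Markers of other cells went down alongside these genes: 14 of 14 B cell markers and 17 of 18 myeloid and dendritic markers were lower at day 2 than in naive libraries (14 and 17 adjusted over the list alone; adjusted p = 0.308 and 0.275 with an estimated correlation). Cd79a, chosen as a B cell marker after its values were seen, was 39.4 ± 23.7 CPM in naive and 5.11 ± 0.812 CPM in OVA day 2 libraries, and Lyz2 was 185 ± 181 and 1.44 ± 0.709 CPM. Naive replicate 3 held the most of both, with 66.6 CPM of Cd79a and 394 CPM of Lyz2; without it Cd79a fell 5.18-fold.

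Q4 and V4 at day 2 were compared with naive cells in the same way. Q4 changed 10640 genes (5536 higher, 5104 lower) and V4 changed 9795 (5192 higher, 4603 lower). With V4, all 20 G2/M genes rose (20 adjusted over the list alone, median 5.23) and Gzmb rose by 8.28 ± 0.16, while St6gal1 fell by 1.22 ± 0.10 and Klf2 by 1.82 ± 0.09. With Q4, St6gal1 fell by 3.44 ± 0.11. Interferon-stimulated genes were lower than naive with V4, 16 of 22 down and 4 up (16 and 4 adjusted over the list alone), with Ifit1 down by 3.12 ± 0.21, although not with an estimated correlation (adjusted p = 0.139 with an estimated correlation). B cell markers were lower in 13 of 14 and higher in 1 with V4 (13 and 1 adjusted over the list alone; adjusted p = 0.344 with an estimated correlation), with Cd79a at 4.4 ± 0.302 CPM (5.96-fold below naive without naive replicate 3), and myeloid markers were lower in 16 of 18 (16 adjusted over the list alone; adjusted p = 0.199 with an estimated correlation). With Q4, 14 of 14 B cell markers and 17 of 18 myeloid markers were lower (14 and 17 adjusted over the list alone; adjusted p = 0.344 and 0.265 with an estimated correlation).

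Each day 1 group was also set against naive cells, across the 2 tables, where batch cannot be told apart from time. At day 1 of OVA, Gzmb rose 1070-fold, Lag3, an inhibitory receptor, 155-fold, Tg 295-fold (491-fold without naive replicate 2), Bcat1 150-fold and the transcription factor gene Batf3 110-fold (300-fold without naive replicate 1). Jchain fell 202-fold, Vipr1 111-fold, Slc28a2b 99.4-fold, Itgae 90.6-fold and Lyz2 89.6-fold (38.5-fold without naive replicate 3). Of 15630 genes, 11673 changed with OVA (6117 higher, 5556 lower), 11633 with Q4, 11998 with V4, 11867 with beads and 11778 with anti-CD3. St6gal1 fell by 3.66 ± 0.15 with OVA, 3.14 with Q4, 1.63 with V4 and 2.41 with anti-CD3. B cell markers were lower with OVA in 13 of 14 and myeloid markers in 17 of 18 (13 and 17 adjusted over the list alone; adjusted p = 0.268 and 0.169 with an estimated correlation). The same numbers were 13 and 17 with Q4, 13 and 16 with V4, 13 (and 1 higher) and 17 with beads, and 13 and 17 with anti-CD3, all unchanged when adjusted over the list alone (adjusted p = 0.263 and 0.176, 0.333 and 0.26, 0.409 and 0.193, and 0.402 and 0.207 with an estimated correlation).

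Q4 was compared with OVA on each day to show what this change of the peptide did at matched times. At day 2, Q4-stimulated cells held more Klf2 (2.79-fold, adjusted p = 2.4e-06), more of the transcription factor gene Eomes (2.31-fold), and more Ccdc141 (3.96-fold), Ifi203 (2.64-fold) and Itih5 (2.32-fold, adjusted p = 0.04). Itih5 missed the threshold when any of the 6 libraries was left out (log2 difference from 1.10 without OVA day 2 replicate 2 to 1.29 without OVA day 2 replicate 3), with DESeq2 (adjusted p = 0.13) and with no filter on low counts (adjusted p = 0.184; from 8.07e-10 to 0.212 over the alternatives). They held less Il23a, a cytokine subunit (6.48-fold lower), Ramp3 (3.70-fold), Gzma (2.45-fold), Lad1 (2.42-fold) and Rgs2 (2.40-fold). In all, 304 of 15069 genes passed, 213 higher and 91 lower, and 1769 had an unadjusted p under 0.05. With DESeq2 564 genes passed, 346 higher and 218 lower. With only the compared groups in the fit 1199 passed, 620 higher and 579 lower. Each fit without 1 of the 6 libraries gave fewer than 304, 130 without Q4 day 2 replicate 3, 134 without OVA day 2 replicate 2, 137 without OVA day 2 replicate 1, OVA day 2 replicate 3 or Q4 day 2 replicate 2, and 148 without Q4 day 2 replicate 1. In the naive list 5 of 20 were higher and 1 lower, and in the activation list 1 of 20 was lower; adjusted over the list alone these were 7 and 6, and 6. The naive list had a median of -0.0404 while camera's direction was up (adjusted p = 0.145). B cell markers (1 of 14 higher, 2 adjusted over the list alone, median 0.565) and myeloid markers (0 of 18 past the threshold, 0 adjusted over the list alone, median 0.442) passed the list test (adjusted p = 0.495 and 0.565 with an estimated correlation). Lyz2 was 9.4 ± 2.92 CPM with Q4 and 1.44 ± 0.709 CPM with OVA, a log2 difference of 2.72 ± 1.01 (adjusted p = 0.321), and passed with DESeq2 and with only the compared groups in the fit (both 2.71; adjusted p from 3.11e-06 to 0.649 over the alternatives). The activation list passed its test (adjusted p = 0.000269), but no list did with an estimated correlation (adjusted p = 0.479 for the activation list with an estimated correlation).

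At day 1, Q4-stimulated cells held more Ccdc141 (6.64-fold, adjusted p = 4.7e-15), Fosb (2.99-fold), Tbc1d4 (2.52-fold) and Ak4 (2.46-fold). Ramp3 (5.06-fold), Acsl6 (3.62-fold), Lad1 (2.63-fold), Sema4c and Ptger2 (both 2.23-fold) were lower. Cholesterol synthesis and uptake genes were higher in 13 of 20 (16 adjusted over the list alone), with Cyp51 up by 0.75 ± 0.08, and this list held with an estimated correlation (adjusted p = 0.0349 with an estimated correlation). Glycolysis genes rose in 7 of 20 (11 adjusted over the list alone; adjusted p = 0.326 with an estimated correlation), with the glucose transporter gene Slc2a1 up by 0.64 ± 0.09. Interferon-stimulated genes fell in 9 of 22 and rose in 2 (14 and 2 adjusted over the list alone; adjusted p = 0.133 with an estimated correlation), with Irf7 down by 0.74 ± 0.11. The count was 979 genes (509 higher, 470 lower). It was 504 without Q4 day 1 replicate 3, 521 without OVA day 1 replicate 3, 537 without Q4 day 1 replicate 2, 598 without Q4 day 1 replicate 1 and 1624 without OVA day 1 replicate 2. Lyz2 was 7.32 ± 1.47 CPM with Q4 and 2.09 ± 0.923 CPM with OVA (1.82 ± 0.23, adjusted p = 2.9e-05).

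V4 against OVA at day 2 showed a broad difference. Klf2 was 24.2-fold higher (132 ± 14.8 against 5.61 ± 0.2 CPM, adjusted p = 1.6e-14), S1pr1 14.2-fold, Slc28a2b 25.8-fold, Ifi203 13.9-fold and Ccdc141 12.7-fold. Lif was 33.8-fold lower and Cish, a feedback inhibitor of cytokine signalling induced by STAT5, 21.3-fold lower. Cth, which makes cysteine by transsulfuration, was 19.1-fold lower, the mitochondrial folate enzyme gene Aldh1l2 12-fold and Rgs16 11.8-fold. In all, 6750 of 15069 genes passed, 3437 higher and 3313 lower.

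T cell receptor-induced activation genes were lower with V4 in 17 of 20 and higher in 1 (17 and 2 adjusted over the list alone), with Nr4a3 down by 2.74 ± 0.08, Egr1 by 3.35 ± 0.13 and Cd69 by 1.86 ± 0.07. Ribosome biogenesis genes fell in 19 of 20 (19 adjusted over the list alone, median -1.27), such as Dkc1 (by 1.45 ± 0.06), and amino acid stress genes in 14 of 15 (14 adjusted over the list alone), such as Trib3 (by 1.33 ± 0.06). Serine and one-carbon genes fell in 14 of 16 and rose in 1 (14 and 1 adjusted over the list alone), and IL-2 and STAT5 targets fell in 8 of 14 and rose in 5 (8 and 5 adjusted over the list alone). Naive genes rose in 13 of 20 and fell in 4 (13 and 4 adjusted over the list alone). G2/M genes rose in 14 of 20 (16 adjusted over the list alone), with Mki67 at 1260 ± 73.9 against 727 ± 16.9 CPM. These 7 lists held with an estimated correlation. Effector genes fell in 15 of 20 and rose in 3 (15 and 3 adjusted over the list alone; adjusted p = 0.109 with an estimated correlation), with Tbx21, the type 1 effector regulator, down by 1.47 ± 0.11 and Prdm1, encoding the transcription factor Blimp-1, up by 2.85 ± 0.21. Among glycan genes, Cmah rose by 2.21 ± 0.06, B4galt1, which adds the galactose that St6gal1 modifies, by 1.21 ± 0.07 and St8sia4 by 0.98 ± 0.11, while St6galnac4 fell by 1.09 ± 0.09. The sialyltransferase, sialic acid supply, N-glycan and O-glycan lists did not pass the list test (camera adjusted p = 0.346, 0.128, 0.346 and 0.382). At day 1 the means of V4 and OVA were 105 and 100 CPM for Cmah and 142 and 198 CPM for B4galt1. They were 78.3 and 92.7 CPM for St8sia4 and 77.5 and 62.4 CPM for St6galnac4. Lyz2 was 24.6 ± 3.75 CPM with V4 and 1.44 ± 0.709 with OVA, and Ighm 829 ± 49.0 and 225 ± 23.0 CPM.

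V4 against Q4 at day 2 gave 5694 genes (2802 higher, 2892 lower). Klf2 was higher by 3.11 ± 0.10 and S1pr1 by 3.33 ± 0.11, and Nr4a3 fell by 2.46 ± 0.08 and Cth fell by 3.44 ± 0.14. Ribosome biogenesis genes were lower in 19 of 20 and G2/M genes higher in 17 of 20 (19 and 17 adjusted over the list alone), and both lists held with an estimated correlation.

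**Figure D2:**
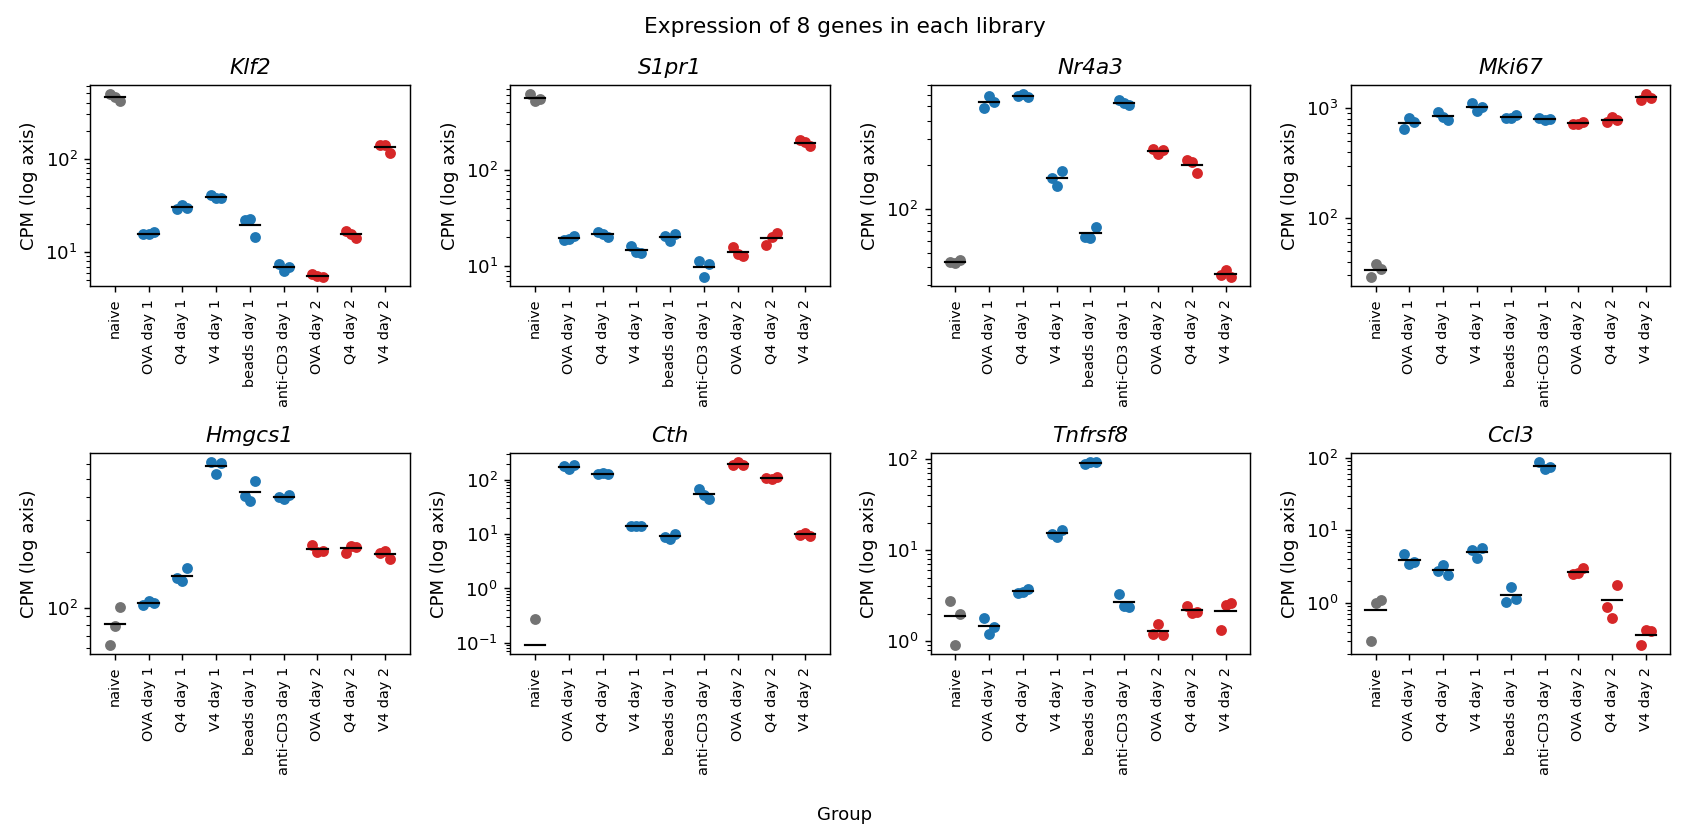
CPM on a log axis (vertical) of 8 genes in each library, by group (horizontal); points are libraries (grey naive, blue day 1, red day 2) and bars are group means; libraries at 0 (2 naive libraries for Cth) are not drawn. In V4 day 2 libraries S1pr1 averaged 194 CPM against 14.1 in OVA day 2, while at day 1 V4 and OVA averaged 14.6 and 19.5 CPM.

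V4 was compared with OVA at day 1 in the same way. Cholesterol synthesis and uptake genes were higher in 20 of 20 (20 adjusted over the list alone, median 1.51), with Hmgcs1 at 588 ± 47.0 against 105 ± 2.58 CPM. Prdm1 was 10.1-fold higher, Emilin2 7.46-fold and the zinc transporter gene Slc39a10 7.32-fold. Amino acid stress genes were lower in 14 of 15 (14 adjusted over the list alone, median -2.05), with Cth 12.3-fold lower, Nupr1 10.5-fold and Atf3, a stress-induced transcription factor, 10.4-fold. Ankrd33b was 14.0-fold lower and the activation marker Cd83 12.1-fold lower. These 2 lists held with an estimated correlation (adjusted p = 0.00646 and 0.0126 with an estimated correlation).

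Of 13786 genes, 7095 passed, 3498 higher and 3597 lower. Ribosome biogenesis genes rose in 18 of 20 (18 adjusted over the list alone; adjusted p = 0.0844 with an estimated correlation) and glycolysis genes in 16 of 20 (16 adjusted over the list alone; adjusted p = 0.174 with an estimated correlation), with Slc2a1 up by 1.64 ± 0.09. G2/M genes rose in 15 of 20 and fell in 2 (15 and 2 adjusted over the list alone; adjusted p = 0.214 with an estimated correlation). Activation genes fell in 11 of 20 and rose in 4 (11 and 5 adjusted over the list alone; adjusted p = 0.0627 with an estimated correlation), with Tnfrsf4 down by 2.51 ± 0.09 and the transferrin receptor gene Tfrc up by 2.00 ± 0.10. Naive genes fell in 14 of 20 and rose in 2 (14 and 2 adjusted over the list alone; adjusted p = 0.0609 with an estimated correlation), with the lymph node homing receptor gene Ccr7 down by 2.27 ± 0.10. Inhibitory receptors fell in 7 of 11 and rose in 2 (7 and 2 adjusted over the list alone; adjusted p = 0.0627 with an estimated correlation), with Pdcd1, encoding PD-1, down by 1.89 ± 0.16. Myeloid markers were higher in 10 of 16 and lower in 2 (11 and 2 adjusted over the list alone; adjusted p = 0.335 with an estimated correlation), with Lyz2 at 30.3 ± 1.72 against 2.09 ± 0.923 CPM. Against Q4 at day 1, V4 changed 5820 genes (2838 higher, 2982 lower), with cholesterol genes higher in 20 of 20 and amino acid stress genes lower in 14 of 15 (20 and 14 adjusted over the list alone).

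**Figure D3:**
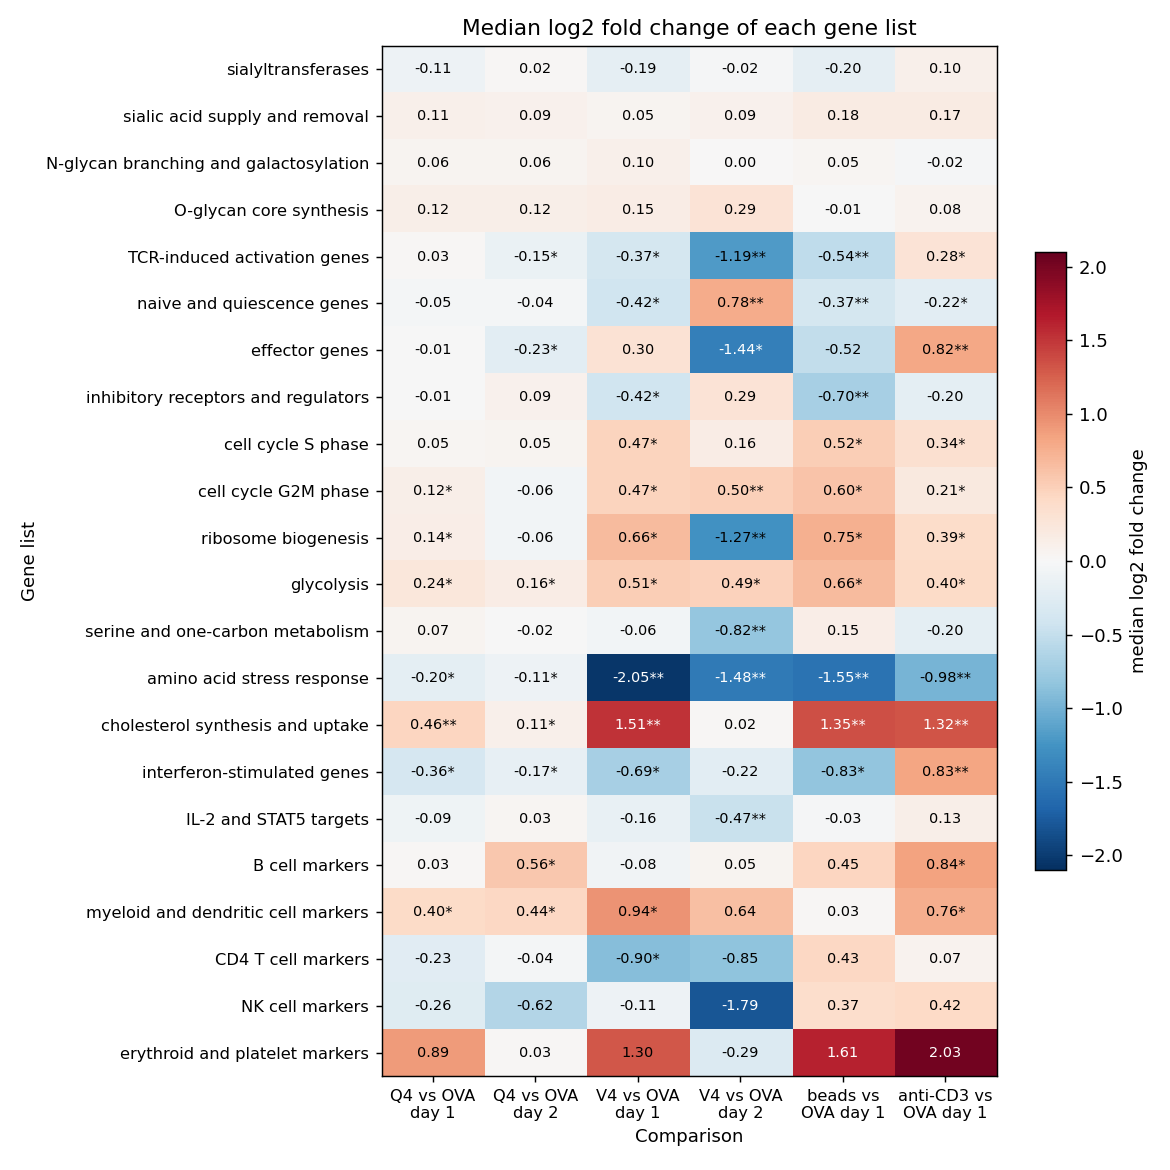
Median log2 fold change (colour and printed value) of each of the 22 gene lists (vertical) in 6 comparisons with OVA of the same day (horizontal); 1 asterisk marks a list past the threshold in camera and 2 asterisks one that also passed with an estimated correlation. Cholesterol genes stand at 1.51, 1.35 and 1.32 in V4, beads and anti-CD3 at day 1, and at 0.0187 in V4 at day 2.

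Beads were compared with OVA at day 1 to set antibody stimulation with CD28 beside the peptide. Tnfrsf8, which encodes the activation receptor CD30, was 62.3-fold higher with beads, Gpr55 29.2-fold, the chemokine receptor gene Cxcr3 15.1-fold and Drc1 8.49-fold. Cth was 19.0-fold lower, Pdcd1 14.2-fold, Nupr1 14.0-fold, the CD28 ligand gene Cd80 13.3-fold and Cd83 11.4-fold. Of 13786 genes, 7219 passed, 3614 higher and 3605 lower. Activation genes fell in 13 of 20 and rose in 5 (13 and 5 adjusted over the list alone), with Nr4a3 at 67.5 ± 6.74 against 537 ± 49.5 CPM, and inhibitory receptors fell in 7 of 11 and rose in 2 (7 and 2 adjusted over the list alone), with Lag3 down by 3.15 ± 0.09. Cholesterol genes rose in 20 of 20, naive genes fell in 14 of 20 and rose in 3, and amino acid stress genes fell in 13 of 15 (20, 14 and 3, and 13 adjusted over the list alone). These 5 lists held with an estimated correlation. Interferon-stimulated genes fell in 13 of 22 and rose in 4 (13 and 4 adjusted over the list alone; adjusted p = 0.101 with an estimated correlation), with Usp18 down by 3.30 ± 0.13. B cell markers were higher in 6 of 13 (6 adjusted over the list alone), but the list did not pass the list test (camera adjusted p = 0.218, and 0.63 with an estimated correlation). Cd79a was at 7.92 ± 2.56 against 5.06 ± 0.451 CPM (log2 difference 0.39 and not past the threshold without beads replicate 2).

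Anti-CD3 was compared with beads and with OVA, all at day 1. Against beads, anti-CD3 gave 59.2-fold more Ccl3, 38.8-fold more Xcl1 and 31.6-fold more Ccl4, which encode chemokines, with Rgs16 26.8-fold and Nr4a2 24.7-fold higher. Tnfrsf8 was 33.3-fold lower, Gpr55 15.8-fold, Drc1 9.85-fold, Cxcr3 9.37-fold and Fosb 6.34-fold. Interferon-stimulated genes were higher in 20 of 22 (21 adjusted over the list alone), with the antiviral gene Mx1 at 64.2 ± 9.85 against 4.4 ± 1.01 CPM. Effector genes were higher in 14 of 20 and lower in 4, activation genes higher in 13 of 20 and lower in 4, and inhibitory receptors higher in 8 of 11 and lower in 2 (14 and 4, 14 and 4, and 8 and 2 adjusted over the list alone). These 4 lists held with an estimated correlation, and 4897 genes passed in all (2503 higher, 2394 lower).

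Against OVA at day 1, anti-CD3 gave higher effector genes in 15 of 20 and lower in 1 (15 and 1 adjusted over the list alone), with Ccl3 up by 4.31 ± 0.15 and the pore-forming gene Prf1 by 2.67 ± 0.10. Interferon-stimulated genes rose in 20 of 22 (20, with 1 lower, adjusted over the list alone), cholesterol genes in 19 of 20 (19 adjusted over the list alone), and amino acid stress genes fell in 13 of 15 (13 adjusted over the list alone), with Cth down by 1.64 ± 0.11. All 4 lists held with an estimated correlation. The count was 4696 genes, 2490 higher and 2206 lower. B cell markers were higher in 7 of 13 and lower in 1 (7 and 1 adjusted over the list alone; adjusted p = 0.366 with an estimated correlation), with Cd79a at 9.35 ± 0.501 CPM.

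The days were compared for each peptide across the 2 tables, where batch cannot be told apart from time. From day 1 to day 2, 5715 genes differed with OVA (2791 higher, 2924 lower), 5686 with Q4 (2750 higher, 2936 lower) and 9186 with V4 (4752 higher, 4434 lower). With V4, ribosome biogenesis genes were lower at day 2 in 20 of 20 and activation genes in 20 of 20 (20 and 20 adjusted over the list alone), with Dkc1 down by 1.95 ± 0.06 and Nr4a3 by 2.18 ± 0.09, and naive genes were higher in 15 of 20 and lower in 2 (16 and 2 adjusted over the list alone), with S1pr1 up by 3.73 ± 0.12. These 3 lists held with an estimated correlation. With OVA, glycolysis genes were lower in 11 of 20 and higher in 2 (11 and 2 adjusted over the list alone; adjusted p = 0.473 with an estimated correlation), with Aldoa down by 1.12 ± 0.09, and Ctla4 was down by 1.22 ± 0.07. St6gal1 rose by 0.43 ± 0.13 with V4 (adjusted p = 0.0063), and did not pass without V4 day 2 replicate 3 (0.31; adjusted p from 7.96e-05 to 0.081 over the alternatives). The St6gal1 difference was 0.21 with OVA (interval -0.12 to 0.53), which passed without OVA day 1 replicate 1 (0.44; adjusted p from 0.0276 to 0.834 over the alternatives), and -0.26 with Q4 (interval -0.57 to 0.04).

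The V4 minus OVA difference was then tested for a change between the days, in 1 fit over both tables. It changed in 6848 of 15630 genes, toward higher with V4 at day 2 in 3425 and toward lower in 3423, which is a direction and not a size. Ribosome biogenesis genes moved down in 20 of 20 and cholesterol genes in 17 of 20 (20 and 17 adjusted over the list alone), while naive genes moved up in 15 of 20 and down in 2 (16 and 2 adjusted over the list alone); these lists held with an estimated correlation. For St6gal1 the change was 0.23 (interval -0.19 to 0.65, adjusted p = 0.402), and without OVA day 1 replicate 1 it was -0.046.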

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

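The test of other splits of the libraries was chosen before the data were examined, and the count of genes that went in opposite directions on the 2 days only after the result was seen. The V4 minus OVA difference changed between the days in 6848 genes and in 7 gene lists, by the test of the difference itself. Of the 3972 genes past the threshold in V4 against OVA on both days, whatever this test gave, 1991 went in opposite directions and 1981 in the same direction. Of 40 splits drawn, 1, the real one, gave as many genes, and the highest other gave 3867. The splits exchange V4 and OVA labels within each day, so they bear on whether the peptides differ at all. They cannot decide whether that difference changed between the days. A shift between the tables that acts alike on V4 and OVA cancels in the test of the difference itself. A batch that acts on the 2 peptides differently cannot be told apart from time.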

How the results depend on the processing

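Most results kept their direction and their side of the threshold under the alternatives, and the exceptions follow. With an estimated correlation the number of lists past the threshold stayed the same only in the change of the V4 minus OVA difference between the days (7). It fell by at most 1.5 times in 8 comparisons: from 14 to 10 in OVA day 2 and in OVA day 1 against naive, from 15 to 10 in Q4 day 2, Q4 day 1 and V4 day 1 against naive, from 14 to 11 in anti-CD3 against naive, from 9 to 7 in V4 against OVA at day 2 and from 8 to 7 in V4 against Q4 at day 2. It fell by more, or to 0, in 12: to 9 in V4 day 2 and in beads against naive, 0 in Q4 against OVA at day 2 and in day 2 against day 1 for OVA and Q4, 1 in Q4 against OVA at day 1, 2 in V4 against OVA at day 1, 5 in V4 against Q4 at day 1, beads against OVA and V4 day 2 against day 1, and 4 in anti-CD3 against OVA and against beads. Q4 against OVA at day 2 gave 564 genes with DESeq2, 478 with no filter and 1199 with only the compared groups in the fit. Leaving out each replicate gave 130 to 148 genes there (all 6 fits under the 304 of the full set; 130 without Q4 day 2 replicate 3) and 5 to 8 lists (5 without Q4 day 2 replicate 3). For Q4 against OVA at day 1 it gave 504 (without Q4 day 1 replicate 3) to 1624 genes (without OVA day 1 replicate 2), with 521 without OVA day 1 replicate 3, 537 without Q4 day 1 replicate 2 and 598 without Q4 day 1 replicate 1, and 4 (without OVA day 1 replicate 2) to 7 lists. The cause was not tested.

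St6gal1 in Q4 against OVA at day 1 passed with DESeq2 (0.51) and with no filter (0.52), and ranged from 0.38 to 0.77 (passed without OVA day 1 replicate 1) over the fits without 1 replicate. At day 2 this difference ranged from -0.027 (without OVA day 2 replicate 2; -0.017 without Q4 day 2 replicate 2) to 0.11. Day 2 against day 1 ranged from 0.056 to 0.44 for OVA (passed without OVA day 1 replicate 1) and from 0.31 (not past without V4 day 2 replicate 3) to 0.53 for V4, and the change of the V4 minus OVA difference from -0.046 (without OVA day 1 replicate 1) to 0.34. Of the other named genes, Itih5 in Q4 against OVA at day 2 missed the threshold in 9 alternatives (DESeq2, no filter, the replicate block and all 6 fits without 1 replicate) and Cd79a in beads against OVA in 1, while Lyz2 in Q4 against OVA at day 2 passed in 2 (2.71 with DESeq2 and with only the compared groups in the fit). The labels do not say whether replicate numbers pair the libraries, and no pairing was seen. Over 36 pairs of groups the correlations of same-numbered libraries' deviations ran from -0.11 to 0.11. In none were all 3 over 0.1, and in 2 every library correlated best with its own number. With 3 libraries per group these correlations cannot exclude a pairing. With a replicate block the gene counts were 0.839 to 0.995 of those reported, the lists past the threshold went from 10 to 9 in anti-CD3 against beads and kept their number elsewhere, and Itih5 (1.22, adjusted p = 0.0838; 8.07e-10 to 0.212 over the alternatives) was the only call of a named gene that changed. RLE scaling moved the median log2 fold change of OVA and Q4 day 1 against naive by -0.1. Like TMM, RLE takes most genes as unchanged, so it does not test that assumption.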

Other observations

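Of the tests below, that of other splits was chosen before the data were examined. Those of library scaling and of thyroid genes address patterns already seen in the data, and were chosen before their own results were seen. Those of B cells, of the mixture, of Sla and of the relation to activation genes were chosen only after the result was seen. St6gal1 was higher in beads and V4 libraries than in OVA libraries of the same day. B cells, which also express St6gal1, would raise their other abundant genes by about as much, but the largest of the 3 medians of B cell markers was 0.451, against lower bounds for St6gal1 of 3.19 with beads, 1.69 with V4 at day 1 and 2.06 with V4 at day 2, and the upper bounds of 13 of 13, 12 of 13 and 11 of 14 markers lay below these. The highest marker was Bank1 with beads (1.53) and with V4 at day 1 (1.36), and with V4 at day 2 Ighd (2.20) and Ighm (1.92) rose by about as much as St6gal1 and Bank1 also rose (adjusted p = 0.000533), while Cd79a (-0.18, interval -0.98 to 0.63) did not pass; why these 3 rose was not tested. RLE scaling moved the St6gal1 difference by at most 0.0059. RLE shares with TMM the assumption that most genes are unchanged, so this small move cannot test that assumption. That these stimuli act on St6gal1 differently from OVA stays open as a hypothesis.

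For the fall of St6gal1 from naive to OVA day 2, B cells in the naive libraries were weighed too: 12 of 14 B cell markers fell by less than St6gal1, with a median of -2.84 against -3.51 for St6gal1. A share of the naive level that comes from B cells cannot be told apart from T cell expression in bulk libraries. Naive replicate 3 held the most Cd79a (66.6 CPM) and the least St6gal1 (157 CPM).

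Across the 8 stimulated groups St6gal1 and the mean of the activation genes had a Pearson correlation of -0.736 (exact p = 0.0327). Anti-CD3 goes against this direction: its activation mean was the highest (0.988), yet its St6gal1 (log2 CPM of 4.97) was above that of OVA day 1 (3.70), OVA day 2 (3.93), Q4 day 2 (3.98) and Q4 day 1 (4.23). The rank correlation was -0.595 (p = 0.132), and a significant rank test was required only after the result was seen. Both p values treat the 8 groups as independent, although OVA, Q4 and V4 each enter on both days. Without V4 day 2 and beads the Pearson correlation was -0.336, so it rests on these groups and the relation cannot be told apart from their other differences.

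Genes of the naive state were higher in V4 day 2 than in OVA day 2 libraries. A mixture of unstimulated cells with cells activated as by OVA would place every gene between these 2 groups. However, 14 of 20 G2/M genes were past the threshold above both, with median log2 differences of 0.502 from OVA day 2 and 5.23 from naive. A mixture with cells in another state, and an effect of the peptide, stay open as untested.

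Tg rose 384-fold from naive to OVA day 2, from 1.44 to 569 CPM (648-fold without naive replicate 2). Reads of Sla, which lies inside Tg on the other strand, would make the genes move together. From naive to OVA day 2 Sla rose as well, 3.2-fold. At day 1 the means of Tg and Sla were 419 and 306 CPM with OVA. Both were lower with Q4 (318 and 270), V4 (189 and 103), beads (93.8 and 113) and anti-CD3 (198 and 253). However, in V4 against OVA at day 2 Sla rose by 0.921 while Tg fell by 1.23 (adjusted p = 2e-04), and 0 exons of Tg overlap Sla. Thyroid tissue would bring its other genes, but of 6 the highest reached 0.051 CPM in OVA day 2 libraries. Part of the Tg exons (112 bp) is shared with Gm17140 on the opposite strand, which was not tested, and no biological explanation was tested.

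For each comparison of 3 against 3 libraries, 1 of 10 splits, the real one, gave as many genes as reported, and 10 splits are too few for a share under 0.05. The highest other split gave 117 genes in OVA day 1 against naive (11673 in the real split), 22 in V4 day 1 against naive (11998), 11 in beads against naive (11867) and in anti-CD3 against OVA (4696), 5 in anti-CD3 against naive (11778), 1 in anti-CD3 against beads (4897) and in V4 day 2 against day 1 (9186). In the other 13 comparisons it gave 0 genes with edgeR: 10865, 10640 and 9795 in the real split for OVA, Q4 and V4 day 2 against naive; 304, 6750 and 5694 for Q4 and V4 against OVA and V4 against Q4 at day 2; 979, 7095 and 5820 for the same at day 1; 7219 for beads against OVA; 11633 for Q4 day 1 against naive; and 5715 and 5686 for day 2 against day 1 with OVA and Q4.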
